A study of Homo sapiens with 24 samples.

How the data were processed

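The data are metabolic labelling RNA sequencing (SLAM-seq) of 24 Jurkat libraries. RNA was made with 4sU present for 2 h, extracted, alkylated, depleted of ribosomal RNA and sequenced, per the labels' protocols. Alkylated 4sU is read as a T-to-C change, which allows reads of new RNA to be told from older RNA. ERCC and a mixture of labelled and unlabelled 4sU spike-in RNA were added after extraction. Whether the amount was set per sample, per amount of RNA or per number of cells is not given in the sources used here. STAR 2.7.1a and the genome build GRCh38.p13 are named in the submitters' processing notes, without a role. The counting tool, its use of strand, the annotation release and the method that estimates new RNA are not given in the sources used here. Since strand use is not stated, reads of overlapping or antisense genes, and of near-identical copies, may be split or shared in ways that cannot be checked from the counts.

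The authors deposited 3 tables. The deposited bulk table holds raw counts per gene for 62703 genes and 92 ERCC sequences in all 24 libraries. The deposited nascent table holds estimated counts of new RNA per gene, which are not whole numbers, for 38313 genes in the 18 libraries with 4sU. The deposited ERCC table repeats the counts of the 92 ERCC sequences for the same 18 libraries. Replicates were not pooled. The p-values measure the spread between libraries called replicates, and the labels do not say whether these were separate cultures. Library totals differ in each table, so neither was scaled to a common depth. In each library between 3663 and 4687 genes have more nascent than bulk counts, so the nascent values are not a share of the bulk counts, and a share of new RNA per gene was not computed here. Library depth limits precision: bulk totals ran from 21.7 M to 85.3 M counts (M, units of 1e6) and nascent totals from 3.6 M to 20.3 M. The 10 most abundant genes took 2.12% to 3.07% of bulk counts. Counting intervals and floors cover counting error only.

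Libraries were grouped by pool, treatment and 4sU as their titles state. The labels call the replicates biological, and what a replicate number stands for is not stated. No pair of replicates agreed within sampling noise (the lowest chi-square per degree of freedom between bulk counts of 2 replicates of a group was 3.17). Nascent counts were rounded to whole numbers. For nascent and bulk counts separately, the 18 libraries with 4sU were fitted together with edgeR 4.0.16 (R 4.3.3), with 1 mean per group, so that all groups share an estimate of the spread. Genes were kept by edgeR's filterByExpr with its default minimum count of 10, libraries were scaled by TMM, and dispersions and quasi-likelihood fits were robust. Each comparison was a contrast of group means tested with edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Edited against control averages both guides. Standard errors were taken as the absolute log2 fold change over the square root of F. The 4sU comparison used the 12 control libraries in a fit of their own. Log2 CPM values for plots and slopes used a prior count of 2. Total RNA per spike-in was log2 of summed gene counts over summed ERCC counts, compared by exact permutation. The size of the TRAIL response per replicate number was the least squares slope, through the origin, of that number's TRAIL minus mock log2 CPM on the log2 fold changes of genes called in the control libraries without 4sU.

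Replicate numbers come from the labels. They were taken to pair libraries where every correlation of same-numbered libraries' deviations from their group means was over 0.1. This held for bulk TRAIL against mock in every pool (lowest 0.283, 0.284 and 0.126 for control, guide 1 and guide 2), for bulk edited against control with TRAIL (lowest 0.126), and for nascent TRAIL against mock in the control and guide 1 pools (lowest 0.208 and 0.179). It also held for nascent comparisons of each guide with control under TRAIL (0.215 and 0.109), and for the guide 1 interaction (0.166). It did not hold for nascent edited against control with both guides together (0.055) or nascent TRAIL against mock in the guide 2 pool (0.097). Replicate 1 libraries stand apart from the others on the second principal component, which holds 11.9% of the nascent and 18.6% of the bulk variance. All replicate 1 libraries lie below 0 on it, at -18.7 or lower in nascent and -30.3 or lower in bulk RNA, and no other library lies below -0.6.

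Before the data were examined, the groups, tests and alternatives were fixed, together with 21 gene lists and a rule for naming genes: past the threshold, a mean log2 CPM of at least 2, no overlap between the libraries compared, and then the largest changes. The files give only Ensembl identifiers and the reference table used here pairs none of them with symbols. The gene list tests and the edited gene's own level were therefore not analysed here, and by the rule at most 2 identifiers that rose and 2 that fell are printed for a comparison. A few more identifiers outside the rule are printed where a fit called few genes, and are marked as named after their values were seen. The alternatives tried were ERCC scaling, RLE size factors, DESeq2 1.42.0, no filter and a stricter filter of at least 1 CPM, the replicate number as a block, leaving out each library, fits of only the groups compared, a 2-fold threshold, nascent counts scaled by bulk library sizes, and exchanging or leaving out the 2 libraries whose labels disagree. The statistics were tested on simulated counts drawn from the real dispersions and library sizes and 1 real mean per gene over all 18 libraries. Apart from the known changes, the draws held no TRAIL response and no deviation shared by replicate number. In them 50 genes were changed by each of 4 known folds, all picked from genes with a mean log2 CPM of at least 2. These are 13483 of 18372 nascent and 11231 of 21074 bulk genes. Recovery of genes with lower counts was not tested. For control TRAIL against mock in nascent RNA, 52% of genes changed 1.5-fold, 82% of those changed 2-fold and 96% of those changed 4-fold were recovered (50 genes each, 18093 tested), with 1 false call. For the interaction in nascent RNA these shares were 50%, 86% and 100% (18086 tested), with 7 false calls. For edited against control with TRAIL they were 66%, 92% and 100% (18100 tested), with 4 false calls. In bulk RNA the shares were 70%, 94% and 100% for control TRAIL against mock, 76%, 92% and 100% for edited against control with TRAIL, and 44%, 86% and 98% for the interaction (20718, 20726 and 20740 tested). Changes of 1.25-fold were mostly missed, with 0% to 24% recovered. Plots were drawn with matplotlib 3.10.9.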

Results

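Jurkat cells, an established human T lymphocyte line that is sensitive to death receptor ligands, were base-edited as pools. In 2 pools an adenine base editor, which turns A into G, changed TFIIB to D207G, each pool with its own guide (called guide 1 and guide 2 here). TFIIB is a general transcription factor that helps to place RNA polymerase II at promoters. The control pool carried an edit in AAVS1, a locus often used as a harmless target. Each pool was edited to at least 85% and kept for at least 10 days. Cells then received 250 ng/mL TRAIL, a ligand of the TNF family that binds death receptors, or mock diluent for 2 h. During the same 2 h, 300 µM 4-thiouridine (4sU), a uridine analog that marks newly made RNA, was present, except in 6 control libraries without 4sU. The 24 libraries formed 8 groups of 3 replicates. Bulk counts of all gene RNA lay between 21.7 M and 85.3 M per library (M, counts in units of 1e6), with a median of 45.8 M. Estimated counts of new (nascent) RNA, given for the 18 libraries with 4sU, summed to between 3.6 M and 20.3 M. The thinnest library was replicate 3 of guide 2 mock, with 21.7 M bulk and 3.6 M nascent counts. The deepest was replicate 1 of guide 1 mock. ERCC spike-in RNA gave 1.07 M to 2.59 M counts per library. The files name genes by Ensembl identifier and do not pair these with symbols, so groups of genes are described by their behaviour and only a few identifiers are given.

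The first comparison asked how the control pool responded to TRAIL within 2 h. In nascent RNA, 1265 genes rose and 665 fell among 18372 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The rises were larger than the falls, with a median log2 fold change of 1.16 among genes that rose and -0.39 among genes that fell. At least a 2-fold change was reached by 696 of the genes that rose and by 8 of those that fell. In bulk RNA, 2136 genes rose and 1305 fell among 21074 tested, with medians of 0.78 and -0.29. Among the 17058 genes tested in both, 881 rose in both kinds of RNA, 337 fell in both and 1 moved in opposite directions. Across these genes, which are not independent replicates, the nascent and bulk log2 fold changes had a Pearson correlation of 0.90. Both kinds of counts come from the same libraries, so they are not independent measurements.

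The 2 identifiers with the largest nascent rise by the naming rule were almost silent in mock. ENSG00000130222.11 had 0 nascent counts over the 3 control mock libraries and 309 over the 3 TRAIL libraries, at least 131-fold higher against a floor of 3 counts over the group. Its TRAIL level was 12.4 ± 4.89 nascent CPM (SD, n = 3), and its bulk level went from 0.0609 ± 0.0427 to 5.03 ± 1.28 CPM (SD, n = 3 each). ENSG00000261595.1 had 1 count in mock and 345 with TRAIL, a ratio of 437 with a 95% counting interval from 78 to 17300. The same gene had ratios of 423 (interval 117 to 3500) in the guide 1 pool and 437 (78 to 17300) in the guide 2 pool. By the same rule, the 2 identifiers with the largest fall were ENSG00000101888.12, with a log2 fold change of -1 ± 0.27 (SE) and an adjusted p of 0.0238, and ENSG00000269939.1, with -1 ± 0.28 and 0.0272. Called genes outside the rule fell further, down to a log2 fold change of -2.14. ENSG00000101888.12 went from 5.17 ± 0.903 to 2.57 ± 0.485 nascent CPM, and ENSG00000269939.1 from 5.12 ± 1.62 to 2.55 ± 0.414 (SD, n = 3 each). In bulk RNA ENSG00000101888.12 also fell (log2 -0.38 ± 0.08, adjusted p = 0.0038), while ENSG00000269939.1 stood at -0.83 ± 0.31 and did not pass (adjusted p = 0.0785).

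These counts describe each gene relative to the bulk of the transcriptome. Scaled to ERCC spike-in instead, the median control gene shifted by -0.58 (log2) in nascent and -0.49 in bulk RNA, and the calls became 337 higher and 61 lower in nascent and 736 higher and 9163 lower in bulk RNA. With the replicate number as a block as well, added after the data had been examined, ERCC scaling gave 671 higher and 11410 lower in nascent and 914 higher and 12910 lower in bulk RNA. With nascent libraries scaled by the bulk counts, 695 genes were higher and 15 lower. Libraries with the same replicate number deviated together, and with the number as a block 2821 nascent genes rose and 2439 fell, and 4135 bulk genes rose and 3915 fell.

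**Figure D1:**
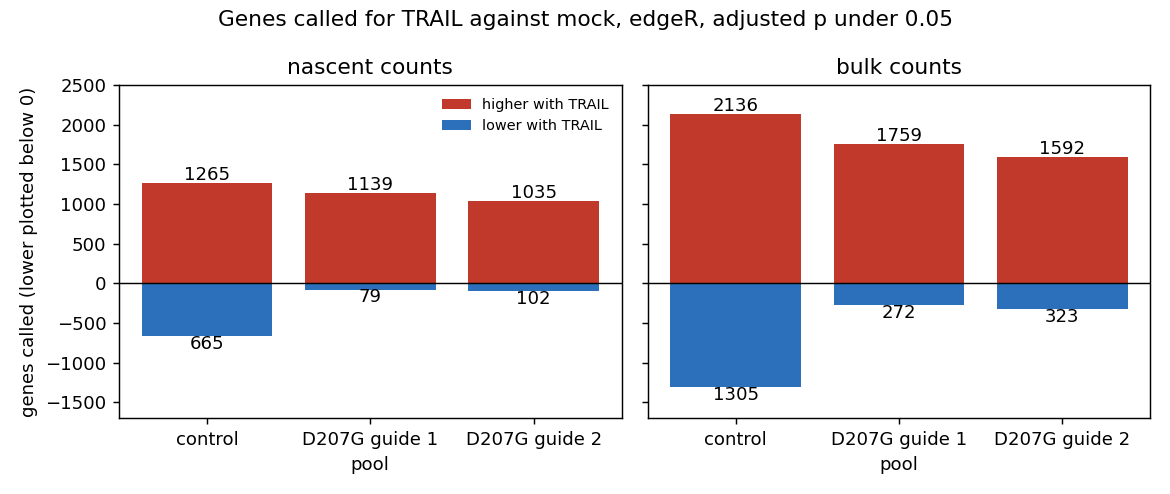
Genes called for TRAIL against mock in each pool (bars above 0: higher with TRAIL, bars below 0: lower; y axis, number of genes), for nascent counts (left) and bulk counts (right), each pool with 3 TRAIL and 3 mock libraries. Genes called lower number 665 in the control pool and 79 and 102 in the guide 1 and guide 2 pools in nascent RNA. Leaving out each library of a comparison in turn, these numbers ranged over 140 to 853, 16 to 381 and 23 to 162.

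The same comparison was made in each edited pool. With TRAIL, 1139 nascent genes rose and 79 fell in the guide 1 pool, and 1035 rose and 102 fell in the guide 2 pool. The median log2 fold change of the genes that rose was 1.64 and 1.67. Each median is over the genes called in its own pool, so these do not show a larger rise than the 1.16 of the control pool. In bulk RNA 1759 genes rose and 272 fell in the guide 1 pool, and 1592 rose and 323 fell in the guide 2 pool. ENSG00000130222.11 and ENSG00000261595.1 rose in both edited pools. ENSG00000101888.12 and ENSG00000269939.1 had nascent log2 fold changes of -0.48 and -0.64 in the guide 1 pool and of -0.69 and -0.63 in the guide 2 pool, and did not pass there. Under ERCC scaling the nascent calls were 545 higher and 6236 lower for guide 1 and 391 higher and 60 lower for guide 2, and the bulk calls 770 higher and 14123 lower, and 783 higher and 8287 lower. The contrast between the guides in nascent RNA is one of the fit without a block: with the block, ERCC scaling gave 719 higher and 14343 lower for guide 1 and 734 higher and 12078 lower for guide 2, and without it 92.2% and 90.6% of all nascent genes had a negative fold change. With the replicate number as a block, the guide 1 pool gave 2008 nascent genes higher and 962 lower, and the bulk calls were 3404 higher and 2543 lower for guide 1 and 3209 higher and 2463 lower for guide 2.

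The responses of the 3 pools overlapped. In nascent RNA 761 genes rose in all 3 pools and 12 fell in all 3, and in bulk RNA 1211 rose and 145 fell in all 3. Of the 1265 nascent genes that rose in the control pool, 850 also rose in the guide 1 pool, where independent lists of these sizes would share 78.4, and 811 rose in the guide 2 pool, where independent lists would share 71.3. Of the same 1265 genes, 98.7% had a positive fold change in the guide 1 pool and 99.1% in the guide 2 pool. Of the 665 genes that fell in the control pool, 98.2% and 97.7% had a negative fold change in the guide 1 and guide 2 pools, although few passed there. The pools share no libraries in these comparisons. Over the 2400 genes called in any pool, nascent fold changes of control and guide 1 had a Pearson correlation of 0.944 and a Spearman correlation of 0.947 across genes, and those of the edited pools with each other 0.960 and 0.967. Over all 18372 genes tested these were lower, at 0.881 and 0.643 for control and guide 1 and 0.902 and 0.650 for the edited pools. The slopes that follow are over the called genes. The total least squares slope of guide 1 on control was 1.05 and that of guide 2 on control 1.06. In bulk RNA, over 3979 genes, these slopes were 1.06 and 1.05.

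Genes were also grouped, after the data had been examined, by a nascent-to-bulk index, the mean log2 nascent CPM minus the mean log2 bulk CPM. Genes high in this index have high nascent counts relative to their bulk counts. Nascent counts exceed bulk counts for many genes, so the index is not a share of new RNA. How well it follows the amount of new RNA was not tested. For each pool the index and the abundance were taken from the mock libraries of the other two pools, which take no part in the comparison, and 17058 genes were split by rank into 5 classes, class 5 being the highest. Of the 3412 genes in class 5, 457 rose in nascent RNA of the control pool (13.4%), against 116 of 3412 in class 1 (3.4%). The odds ratio of rising in class 5 against the rest was 2.66 (95% interval 2.35 to 3.01), and 2.42 (2.13 to 2.74) within 5 classes of abundance. It was 3.43 in the guide 1 pool and 3.24 in the guide 2 pool, and 2.77 and 2.65 within classes of abundance. Genes that fell lay more often in class 1, with 202 of 3412 genes there in the control pool, an odds ratio of 1.87 (1.57 to 2.22), and 1.52 (1.28 to 1.81) within classes of abundance. In the guide 1 pool the latter value was 1.55, with an interval (0.963 to 2.5) that includes 1. In bulk RNA 568 genes of class 5 rose in the control pool and 494 of class 1 fell, with odds ratios within classes of abundance of 1.29 and 1.47. The intervals treat genes as independent, which they are not.

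**Figure D2:**
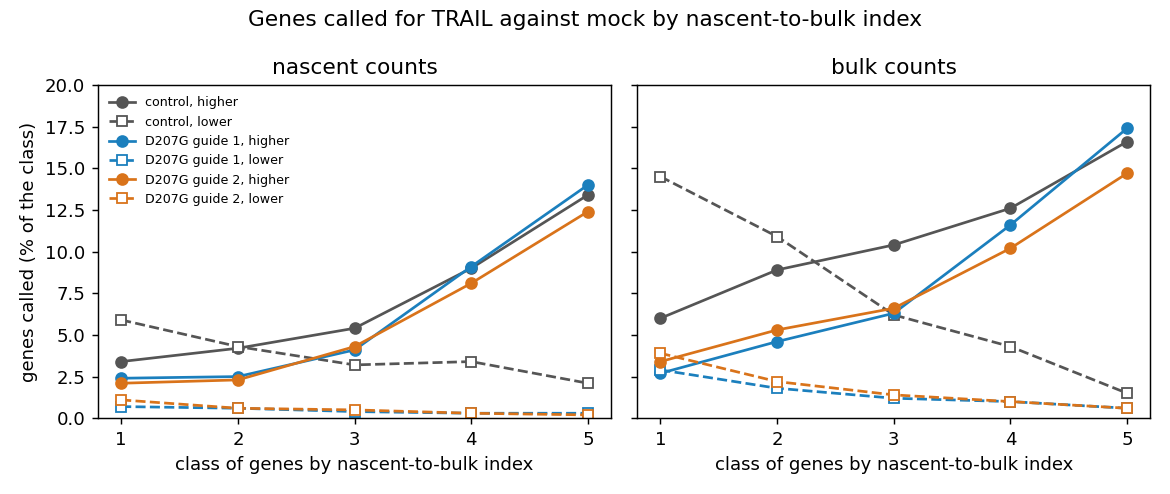
Share of genes called higher (solid lines, filled points) or lower (dashed lines, open squares) with TRAIL in each of 5 classes of genes by nascent-to-bulk index in mock libraries of the other pools (x axis; 5 is the highest index; y axis, percent of the genes in the class), for nascent (left) and bulk counts (right). In nascent RNA the share called higher goes from 3.4% to 13.4% in the control pool.

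The effect of the edit without TRAIL was read from the mock libraries of both edited pools against the control pool. No gene passed in nascent RNA (0 of 18372 by edgeR) or in bulk RNA (0 of 21074). At an unadjusted p under 0.05 there were 396 nascent and 353 bulk genes, and DESeq2 also called 0 in each. The fits still bound the differences. The median 95% half-width was 0.30 (log2) for nascent and 0.31 for bulk genes, and 98.7% of the 13483 nascent genes with a mean log2 CPM of at least 2 had an interval wholly inside 2-fold either way. Taken singly and without a block, neither guide gave a call in mock, with 463 and 293 nascent genes at an unadjusted p under 0.05 for guide 1 and guide 2, and 363 and 387 bulk genes. DESeq2 called 1 bulk gene lower for guide 2. With the replicate number as a block, which pairs the mock libraries of guide 1 and control, guide 1 gave 0 nascent and 0 bulk genes. In bulk RNA the numbers do not pair the mock libraries of guide 2 with control by the rule used, and the block there called 6 genes lower, and 3 lower for both guides together.

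Under TRAIL, the main fit called no gene between edited and control pools. Calls came only from alternative fits, with the most when the replicate number was a block. Many of the genes that the blocked fit called higher in the edited pools were genes that TRAIL itself raises. Without the block, 0 nascent and 0 bulk genes passed, with 539 and 733 at an unadjusted p under 0.05, and DESeq2 called 1 nascent and 20 bulk genes. In simulated nascent counts for this comparison 92% of genes changed 2-fold and 66% of genes changed 1.5-fold were recovered (50 genes each, 18100 tested). All of the changed genes had a mean log2 CPM of at least 2. In bulk RNA the replicate numbers pair the libraries of this comparison, and with the number as a block 146 genes were higher and 48 lower in the edited pools. Another assignment of the libraries within replicate numbers called 153 bulk genes, close to the 194 of the real one. The libraries come from 2 edited pools and a single control pool, so the p-values do not measure the spread between pools. Both the higher and the lower calls depend on the fit: ERCC scaling with the block gave 25 higher and 10 lower, and leaving out all libraries of replicate number 1 gave 22 higher and 0 lower, both added after the data had been examined. In the fit with the block alone, the median log2 difference was 0.47 among the 146 higher and -0.35 among the 48 lower genes. Of the 145 higher genes that were also tested in control libraries without 4sU, 98 had risen with TRAIL there, against 7.65 for independent lists, and of the 48 lower genes 0 had (2.53 for independent lists). These libraries took no part in the comparison of the pools. This overlap was not counted for other assignments of the libraries within replicate numbers. Genes that TRAIL raises may differ most between any TRAIL libraries, so the overlap is not evidence of a difference between the pools. Guide 1 alone gave 110 higher and 15 lower bulk genes against control with the block, and guide 2 alone 32 and 27. Of the higher genes, 93 of 110 for guide 1 and 17 of 32 for guide 2 had risen in the libraries without 4sU. Independent lists would share 5.81 and 1.69. In nascent RNA the block gave 44 higher genes and 1 lower for guide 1, of which 38 of the 44 had risen in the libraries without 4sU, and 3 higher for guide 2, all 3 of which had. Named after their values were seen, these 3 are ENSG00000288766.1, ENSG00000290056.1 and ENSG00000291006.1 (log2 1.07, 0.98 and 0.53), and the 1 lower for guide 1 is ENSG00000162490.7 (-0.72). Without the block none of the 4 single-guide comparisons under TRAIL gave a call, with 423 and 467 nascent and 560 and 611 bulk genes at an unadjusted p under 0.05, and DESeq2 called 1 nascent gene for guide 1 and 18 and 2 bulk genes for guide 1 and guide 2.

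Other genes differed more, up to a log2 difference of 1.4 among the higher and 1.2 in size among the lower genes, but only those with a mean log2 CPM of at least 2 and no overlap between the libraries compared are named. Within this rule the largest blocked bulk differences were those of ENSG00000182759.4 and ENSG00000289341.2, both 1.71-fold higher in the edited pools with TRAIL. ENSG00000182759.4 stood at 17.3 ± 3.33 CPM (SD, n = 6) in edited and 10.1 ± 2.56 (SD, n = 3) in control libraries, with an adjusted p of 0.0032. ENSG00000289341.2 stood at 24.4 ± 2.26 and 14.3 ± 2.17, with an adjusted p of 0.0303. Both rose with TRAIL in every pool, by a log2 fold change of 5.51 and 4.42 in the control pool. Within the rule the largest falls were those of ENSG00000133216.17, at 19.5 ± 2.14 against 26.1 ± 1.98 CPM (adjusted p = 0.000445), which rose with TRAIL in the control pool (log2 0.31, adjusted p = 0.0391), and ENSG00000151240.17, at 6.19 ± 0.624 against 8.07 ± 1.22 (adjusted p = 0.00855).

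Whether the TRAIL response itself differed was tested as the interaction of edit and treatment. It called 0 genes in nascent and 0 in bulk RNA by edgeR, with 512 and 407 at an unadjusted p under 0.05, and 0 in each by DESeq2. The median 95% half-width of this difference of log2 fold changes was 0.43 in nascent and 0.44 in bulk RNA, without adjustment for the number of genes. It is therefore not a limit of detection. Of simulated genes with a mean log2 CPM of at least 2 and a response changed 1.5-fold, 50% were recovered in nascent and 44% in bulk RNA. Changes of this size could therefore be missed. The larger number of lower calls in the control pool is therefore not shown to be a difference between pools. For guide 1 alone, where the numbers pair the nascent libraries, the block gave 1 gene, ENSG00000291006.1, named after its values were seen. It went from 16.0 ± 0.801 to 99.0 ± 13.9 nascent CPM in the guide 1 pool and from 19.4 ± 2.34 to 59.4 ± 6.96 in the control pool (SD, n = 3 each). The interaction was 1.00 ± 0.13 (log2, SE), with an adjusted p of 3.23e-05 with the block and 0.321 without it. In the guide 2 pool this gene went from 17.6 ± 0.279 to 85.6 ± 12.2 nascent CPM, and its interaction of 0.63 did not pass with the block (adjusted p = 0.504).

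**Figure D3:**
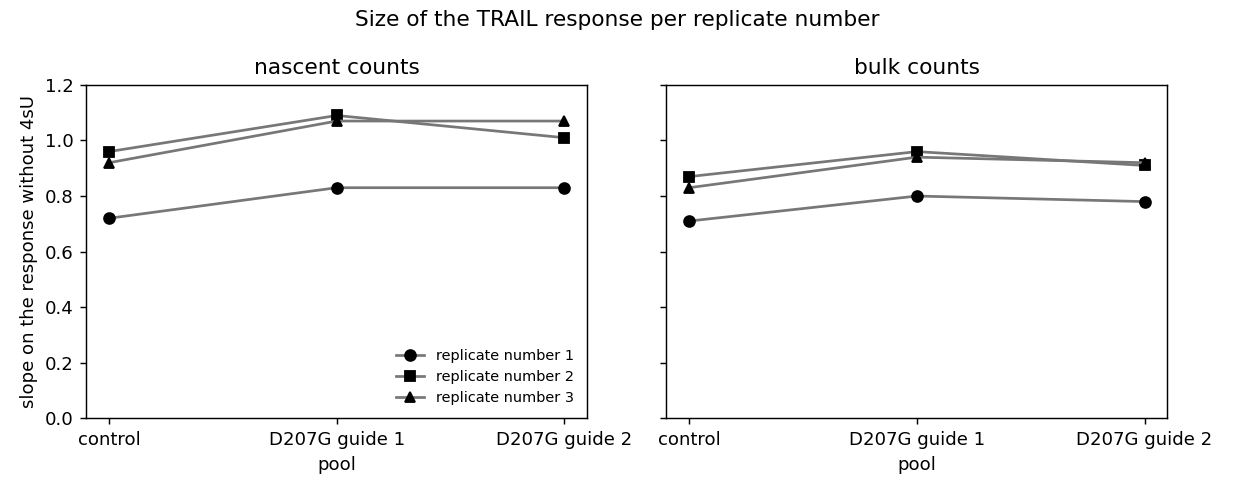
Size of the TRAIL response (y axis, slope of TRAIL minus mock log2 CPM on the response of control libraries without 4sU) for each pool (x axis) and replicate number, for nascent (left, 929 genes) and bulk counts (right, 1109 genes). The control pool has the smallest slope in 3 of 3 replicate numbers in both panels.

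The guides were compared with each other to see whether they gave the same transcriptome. In nascent RNA 0 genes differed between the edited mock pools and 0 in their response to TRAIL, by edgeR and by DESeq2, with 318 and 178 genes at an unadjusted p under 0.05. The median half-width was 0.35 for the mock comparison and 0.50 for the interaction. In bulk RNA 0 genes differed by edgeR in mock (548 at an unadjusted p under 0.05) and 0 in the response (192). The numbers pair the bulk mock libraries of the guides, and with the block 2 genes were higher in guide 1, ENSG00000073792.16 (log2 0.40, adjusted p = 0.0076) and ENSG00000124942.14 (log2 0.30, adjusted p = 0.0246), named after their values were seen. The response slope of guide 2 on guide 1 was 1.01 in nascent and 0.99 in bulk RNA.

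Total RNA per spike-in was lower with TRAIL in all pools. Relative to ERCC counts, nascent RNA with TRAIL was 68.6% of mock in the control pool, 62.3% in the guide 1 pool and 71.8% in the guide 2 pool. Bulk RNA was 71.1%, 63.6% and 74.4%. The guide 2 value depends most on single libraries, with a nascent log2 difference from -0.78 to -0.27 when each is left out. With the median over ERCC species in place of their sum the pools were nearly equal, at -0.79, -0.80 and -0.79 (log2) in nascent and -0.74, -0.77 and -0.74 in bulk RNA for control, guide 1 and guide 2. On the log2 scale, control bulk RNA stood at 4.33 ± 0.06 with TRAIL and 4.82 ± 0.01 in mock (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The guide 1 pool stood at 4.31 ± 0.07 and 4.97 ± 0.14 (exact permutation p = 0.1), and the guide 2 pool at 4.22 ± 0.14 and 4.64 ± 0.26 (exact permutation p = 0.2). For nascent RNA the exact permutation p was 0.1, 0.1 and 0.3. Over the 9 pairs of the same pool and replicate number, 9 of 9 were lower with TRAIL in nascent RNA (mean log2 -0.57 ± 0.18, SD) and 9 of 9 in bulk RNA (-0.52 ± 0.16). Nascent and bulk values share the libraries and the ERCC counts, so they are not separate evidence. Pairs with the same number deviate together, so these are not 9 independent pairs, and within each pool an exact sign-flip test over its 3 numbers gave p = 0.25, the smallest it can give. With both guides averaged, the edited pools did not differ from control beyond the spread between libraries. The tests of this take the libraries of 2 pools as 6 replicates. Without TRAIL the means of the guides lay on opposite sides of control, which the average cancels. Nascent RNA in mock stood at 2.69 in guide 1 and 2.35 in guide 2 against 2.57 in control (log2), and bulk RNA at 4.97 and 4.64 against 4.82. The low guide 2 mean rests mostly on replicate 3, the thinnest library (1.757 in nascent and 4.344 in bulk RNA). Guide 2 replicates 1 and 2 stood near control, at 2.774 and 2.530 against 2.838 and 2.513 in nascent RNA. In bulk RNA they stood at 4.782 and 4.806 against 4.825 and 4.832. Guide 1 lay above control in replicates 1 and 2 but not in replicate 3 (nascent 2.337 against 2.374). In mock, edited nascent RNA was 96.5% of control (exact permutation p = 0.833) and bulk RNA 98.9% (p = 0.798, exact), and with TRAIL 94.0% (p = 0.679, exact) and 95.7% (p = 0.429, exact). The difference of the falls was -0.04 in nascent (p = 0.810, exact) and -0.05 in bulk RNA (p = 0.714, exact). After Benjamini-Hochberg adjustment over the 12 comparisons of this kind the smallest p was 0.3 (exact permutation tests).

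**Figure D4:**
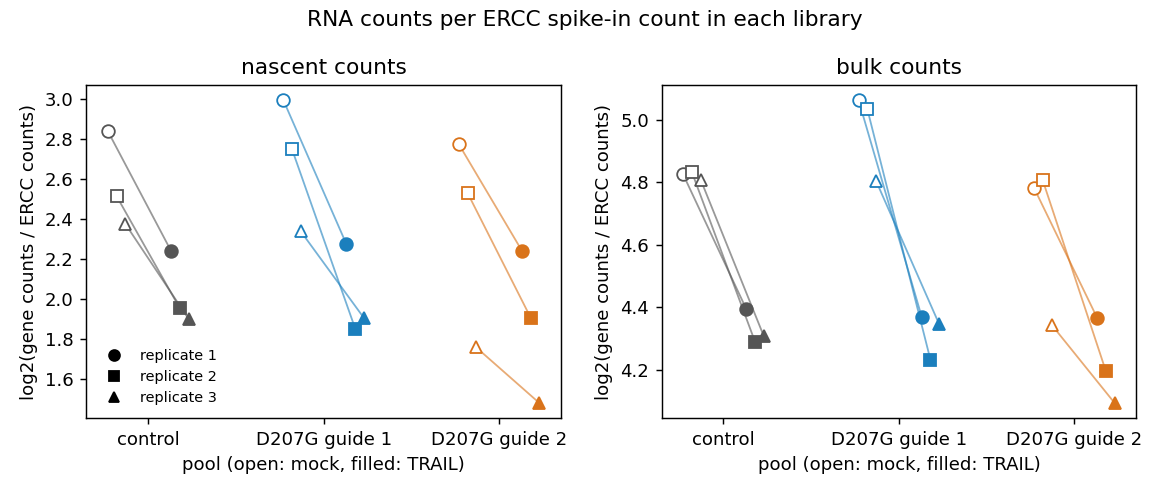
Gene counts per ERCC count (y axis, log2) in each of the 18 libraries with 4sU, for nascent (left) and bulk counts (right), by pool (x axis), with open symbols for mock, filled symbols for TRAIL, a symbol shape per replicate number and a line joining mock and TRAIL of the same number. Each of the 9 lines goes down from mock to TRAIL in both panels.

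The control pool also showed how the label itself bears on bulk counts. With 4sU, 6487 genes were higher and 6554 lower than without it, 60.1% of the 21685 tested. At least 2-fold changes were mostly losses, with 387 genes higher and 2329 lower. Under ERCC scaling 340 genes were higher and 14847 lower. TRAIL raised 1104 genes and lowered 17 in the libraries without 4sU, and 1120 of these 1121 genes had the same sign with 4sU. The small number of lower genes there depends on the fit. The replicate number as a block gave 2104 higher and 450 lower, and ERCC scaling 721 higher and 12700 lower. All settings of the TRAIL response without 4sU were added after the data had been examined. Across genes the TRAIL log2 fold changes with and without 4sU had a Pearson correlation of 0.85 and a Spearman correlation of 0.64. The interaction of 4sU and TRAIL called 0 genes by edgeR, with 607 at an unadjusted p under 0.05. For 2 libraries of this comparison, replicate 1 of control TRAIL with and without 4sU, the titles and the sample characteristics disagree on 4sU. The titles, which the column names of the tables share, were used, and with the 2 exchanged the 4sU comparison called 0 genes, while with both left out it called 13087. Bulk RNA per ERCC count (log2) was 4.39 in the library titled with 4sU and 4.66 in the one titled without, the same order as in replicates 2 (4.29 and 4.49) and 3 (4.31 and 4.73). The library titled with 4sU had 9.7 M nascent counts, near the 10.6 M and 10.2 M of guide 1 and guide 2 TRAIL replicate 1. These values go with the titles.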

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

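The measure of response size, its permutation and the splits within replicate numbers were chosen after the results had been seen, while what thinning and mock baselines would show was written before those values were seen. The size of the TRAIL response differed between edited and control pools by an average slope of 0.11 in nascent RNA (929 genes) and 0.08 in bulk RNA (1109 genes), a difference between groups that shows when the pool labels are permuted within replicate numbers. The nascent slope was 0.87 ± 0.13 (SD, n = 3) in the control pool, 0.99 ± 0.14 in the guide 1 pool and 0.97 ± 0.12 in the guide 2 pool, and the bulk slopes were 0.80 ± 0.08, 0.90 ± 0.09 and 0.87 ± 0.08. The control pool had the smallest slope in 3 of 3 replicate numbers in both kinds of RNA, which come from the same libraries and are not independent results. Of the 27 ways to call 1 pool per number the control, 1 gave a gap as large, the real one, with at most 0.09 among the others in nascent and 0.06 in bulk RNA (exact permutation p = 0.037 in each, the smallest it can give, not adjusted for the 2 tests).

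Library depth is argued against by thinning, after which the control pool was still smallest in 3 of 3 numbers, and the gaps stayed at 0.11 and 0.08. Mock baselines are argued against by their share of the gap, -14.0% in nascent and -30.4% in bulk RNA, which means that the mock libraries lay on the side that lessens it. The edit stays open as a cause, and so does any other difference between 3 pools grown apart, since each guide is a single pool. No test here tells these apart. The response sizes used TMM scaling only, and ERCC scaling of them was not tried. Of the 1121 genes called without 4sU 1104 rose, so a shift in scaling between pools would move the slopes. Against ERCC, nascent RNA fell by -0.54 in the control, -0.68 in the guide 1 and -0.48 in the guide 2 pool (log2). Gene by gene the interaction of both guides called 0 genes by edgeR with the filter and without the block, and 1 nascent gene with the block, without a filter or without replicate number 1, and 2 bulk genes without a filter.

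Other splits of the same libraries were counted for each comparison. For TRAIL against mock, 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real split was 1 of 10 with as many calls in each pool, with 1930, 1218 and 1137 nascent and 3441, 2031 and 1915 bulk genes, and the highest other split called 0 in all 6. For edited against control without the block, the real split called 0, so all 84 splits gave as many in mock and with TRAIL, and all 50 drawn did for each interaction, the guide interaction included. The same was so for all 10 splits of each single-guide comparison and of the guides in mock, with 0 in the highest other. The highest other split called 1352 nascent and 6951 bulk genes in mock and 3907 and 4860 with TRAIL, and in each of these it was the split that sets the 3 replicate 1 libraries against the rest, which points to a structure of the samples by replicate number. The highest of the other draws was 798 genes for the nascent and 158 for the bulk interaction of both guides, 1 and 0 for guide 1, 0 and 1 for guide 2, and 0 between guides. With the number as a block, edited against control with TRAIL called 42 nascent and 194 bulk genes, and 1 of the 27 assignments within numbers gave as many, the real one, with 7 and 153 in the highest of the others. This share is the smallest that 27 assignments can give and is not adjusted for the 2 tests, and in bulk RNA 153 is close to the real 194. The bulk assignment with 153 differs from the real one in replicate 3 alone. By the rule used, the numbers do not pair the nascent libraries of this comparison (lowest correlation 0.055). The nascent count of 42 and its share therefore rest on a pairing that the rule did not find. For the 4sU comparison 1 of 50 splits drawn gave as many as the real 13041, with 5347 in the highest other.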

How the results depend on the processing

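Leaving out replicate number 1, ERCC scaling with the block, ERCC scaling of the 4sU comparison, ERCC scaling and the block for the slopes, and all settings of the unlabelled TRAIL response were chosen after the results had been seen. For each change below the cause was not tested. Where 3 or 6 values follow each other they are for the control, guide 1 and guide 2 pools.

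Requiring 2-fold left 704 nascent control genes and 894, 1027 and 900 bulk genes for TRAIL against mock. ERCC scaling gave 398, 6781 and 451 nascent and 9899, 14893 and 9070 bulk genes. The replicate block gave 5260, 2970 and 2854 nascent and 8050, 5947 and 5672 bulk genes, of which guide 2 nascent had 1940 higher and 914 lower. ERCC scaling with the block gave 12081, 15062 and 12812 nascent and 13824, 17223 and 13737 bulk genes. Without replicate number 1 there were 3222, 2756 and 2027 nascent and 5826, 5593 and 4677 bulk genes. Bulk library sizes left 710 nascent control genes. Fits of only the groups compared gave 1718, 1288 and 1059 bulk genes.

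For edited against control with TRAIL, the block gave 42 nascent and 194 bulk genes, ERCC scaling with the block 11 and 35, leaving out replicate number 1 31 and 22 (none of them lower), no filter 1 and 26, and DESeq2 1 and 20. For guide 1 with TRAIL these were 45 and 125, 14 and 60, 32 and 39, 1 and 26, and 1 and 18. For guide 2 with TRAIL the block gave 3 nascent and 59 bulk genes, ERCC scaling with the block 11 bulk, leaving out replicate number 1 1 nascent, no filter 5 bulk and DESeq2 2 bulk genes. In mock, the block gave 3 bulk genes, and for guide 2 alone 6, with 10 under ERCC scaling with the block, 4 without a filter and 1 by DESeq2. The nascent interaction gave 1 gene with the block, 1 without a filter and 1 without replicate number 1, for both guides and for guide 1, and 1 by DESeq2 for guide 1. Without a filter the bulk interaction gave 2 genes for both guides, 3 for guide 1 and 3 for guide 2.

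For 4sU, 2716 genes were left at 2-fold and 0 with the labels of 2 libraries exchanged. TRAIL without 4sU gave 743 genes at 2-fold, 2554 with the block, 691 with labels exchanged, 2137 without replicate number 1 and 13421 under ERCC scaling. The slope of guide 1 on control was 1.094 under ERCC scaling in nascent RNA.

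Leaving out each library in turn, TRAIL against mock ranged over 805 to 2198, 877 to 1938 and 705 to 1345 nascent genes, and 1829 to 3041, 1288 to 2568 and 1134 to 1721 bulk genes. The nascent control count moved most without replicate 1 or 2 of mock or replicate 2 or 3 of TRAIL (1011, 1242, 805 and 1157). Guide 1 moved without TRAIL replicate 1 in nascent (1938) and TRAIL replicate 2 or 3 in bulk RNA (1315 and 1288). Guide 2 moved without mock replicate 2 (706 and 1134) or TRAIL replicate 3 (705 and 1267), and bulk control without TRAIL replicate 2 (1829) or mock replicate 3 (2249). Nascent edited against control with TRAIL, guide 1 with TRAIL and the guide 1 interaction ranged from 0 to 1, with 1 without guide 1 TRAIL replicate 1. TRAIL without 4sU ranged from 772 to 1039 genes. Leaving out each replicate number in all pools, slopes ranged over 1.018 to 1.072, 1.023 to 1.146 and 1.004 to 1.096 in nascent RNA for guide 1 on control, guide 2 on control and guide 2 on guide 1, and over 1.035 to 1.086, 1.034 to 1.129 and 0.976 to 1.086 in bulk RNA.

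The fall of RNA against ERCC with TRAIL ranged over -0.6482 to -0.4121, -0.8616 to -0.5329 and -0.7766 to -0.2682 in nascent RNA and -0.5238 to -0.4714, -0.7335 to -0.6041 and -0.5766 to -0.3456 in bulk RNA. By the median over ERCC species it was -0.7894, -0.7990 and -0.7884 in nascent and -0.7373, -0.7673 and -0.7367 in bulk RNA.

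RNA against ERCC changed sign for edited against control, over -0.1523 to 0.1016 in nascent mock (0.08006 without control mock replicate 1), -0.1549 to 0.01561 in nascent TRAIL (also 0.003788), -0.09777 to 0.02599 for the nascent interaction, -0.06766 to 0.07605 in bulk mock and -0.1051 to 0.00524 for the bulk interaction.

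Not run were the gene list tests and the level of the edited gene, for lack of symbols, the new share of RNA, since nascent counts exceed bulk counts for many genes, and the exchange of labels for nascent counts, which the unlabelled libraries lack. The planned spike-in alternative by gene type was replaced by leaving out the 10 most abundant genes.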

Other observations

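The correlation with the index, the fall in unlabelled libraries and the ERCC share were chosen after the results had been seen, and leaving out the 10 most abundant genes and thinning before. Bulk counts changed for 13041 genes with 4sU, and reads that carry many T-to-C changes may be lost in mapping or counting. Across 17052 genes the 4sU effect had a Spearman correlation of -0.22 in mock and -0.20 in TRAIL with the nascent-to-bulk index taken from other libraries, which is the direction that loss of labelled reads predicts. Relative to other genes the median effect was 0.37 and 0.28 in class 1 and 0.00 and -0.04 in class 5 (mock and TRAIL), while bulk RNA per ERCC count with minus without 4sU was -0.32 and -0.30 (log2, exact permutation p = 0.1 each). Thinning to the smallest total still called 12690 genes. The control libraries were already close in depth, at 41.2 M to 51.2 M bulk counts with 4sU and 39 M to 49.3 M without. Thinning could therefore hardly change the calls, and no conclusion on depth is drawn from it. A response of the cells to 4sU could give the same correlation (at most 0.22 in size), and the data cannot tell these apart.

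RNA per ERCC count fell with TRAIL in all pools. Without the 10 most abundant genes the control fall in bulk RNA was -0.50. These genes took only 2.12% to 3.07% of bulk counts per library, so leaving them out could hardly change the fall. No conclusion is drawn from it. In control libraries without 4sU the fall was -0.52 (3 of 3 pairs, exact sign-flip p = 0.25), which argues against labelling as the cause. ERCC took 1.41 percentage points more of the counts with TRAIL (4.88% against 3.47%). If each sample got the same amount of spike-in, less extracted RNA with TRAIL could do this, and if not, unequal spike-in could, and the files do not tell these apart.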
